A study of Arabidopsis thaliana with 43 samples.

How the data were processed

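RNA sequencing libraries from Arabidopsis thaliana Col-0 embryos were analysed as gene levels. Per the submitters' processing notes the tools were cutadapt 1.9.1 and kallisto 0.43.1 with genome build TAIR10; their roles, settings and transcript set are not stated there. Each of the 43 deposited tables holds, for the same 54845 transcripts, the authors' estimated counts, the reads that kallisto assigned to each transcript, as deposited and not scaled to depth. It also holds the authors' TPM, which divides by length and sums to a fixed total over every transcript of the table, spike-ins included. The deposited effective length, in bases and of its own kind of unit, was used in 1 alternative only. The tables cover 53685 transcripts of 32507 loci (32222 nuclear, 133 plastid, 152 mitochondrial), 96 spike-in RNAs and 1064 further non-coding RNAs. Kallisto assigns reads shared by similar transcripts by likelihood, so levels of close paralogs (RBCS, SESA, LHCB1, LHCB2, DIR1) and of overlapping genes are uncertain, and the strand of the libraries is not stated. TPM is a share of the total: where storage transcripts fill a library, the TPM of all others falls, whereas the counts were rescaled by TMM factors. Those factors were 0.5527 to 0.6281 at mature green and 0.838 to 1.302 at the other stages.

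Counts and TPM were summed per locus. Symbols came from the RefSeq annotation of assembly TAIR10.1, which lists 32222 of the 32222 nuclear loci and a symbol for 10479; since the build differs in name from the authors', no positions are given. Counts rounded to whole numbers were tested in edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood test), a gene being called at a Benjamini-Hochberg adjusted p under 0.05. All 24 stage libraries were fitted together by stage (21014 genes tested), as were the 12 Smart-seq2 bent-cotyledon libraries by input (17090 genes). Neighbouring stages were compared as steps of the series, preglobular with mature green as its ends, and each lower input with 5 ng. R was 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

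Choices made before the data were examined were the groups, tests, gene lists, naming rule and most alternatives. The 16 gene lists held 318 members: seed storage proteins, oil body proteins, fatty acid and oil synthesis, LEA proteins, maturation regulators, embryo patterning, DNA replication, mitosis, nuclear photosynthesis genes, abscisic acid and gibberellin metabolism, DNA methylation and silencing, small heat shock proteins with their regulators, wound and handling response, endosperm, seed coat and reference genes. CLO2 and SBT1.7 were left out because their loci carry other symbols in the annotation. Plastid- and mitochondrion-encoded genes formed a further pair of lists. The endosperm and seed coat lists stand for tissues beside the embryo. Each list was tested with camera (limma) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, corrected over the lists of a comparison.

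Genes were named by a rule. For preglobular to mature green these were the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 50 CPM in the higher group and no overlap between libraries. For each pair of stages or inputs they were the 3 largest each way, and for each kit against Smart-seq2 the 5 largest each way by the smallest difference over 4 inputs with a mean of at least 50 TPM; any list member could be named too. Folds against a group without counts are bounds against 3 counts over its 3 libraries, and with 1 to 3 counts the fold has a 95% counting interval. Amplified reads are not independent molecules, so intervals and bounds cover counting error only.

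Detected genes have 5 or more counts after thinning at random to a common total (7994611 for stages, 987518 for inputs), compared by exact two-sided permutation tests. Agreement with 5 ng is the Pearson r of log2(TPM + 1) across genes. A gene counted as different between kits when log2(TPM + 1) differed by 2 or more in the same direction at all 4 shared inputs. Shares of TPM were tested with 100000 permutations of 24 libraries over 19 groups.

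Alternatives were RLE size factors, DESeq2 (Wald test for pairs, likelihood-ratio test over the 8 stages), no filter, a filter of 5 CPM in 3 libraries, limma on log2(TPM + 1) and log2(TPM + 0.1), an effective length offset, organelle genes left out, fits of only the groups compared, the replicate number as a block, an added 2-fold minimum, the 1 ng libraries for bent cotyledon and each replicate left out. For kits and detection, other pseudocounts, minimums and size rules were tried. Settings restricted to protein-coding genes were chosen after seeing the data. The pairing of input libraries comes from the labels, which tie a replicate number to 1 RNA. Residuals of the same number correlated at 0.163 on average and of different numbers at −0.0814. Residuals were taken from means of 3 libraries, so the value for different numbers largely follows from the first and adds no evidence. Across stages the number marks no shared RNA, and the values were −0.0149 and 0.00816. Each pair of replicates within a Smart-seq2 group differed by more than sampling noise; other pairs were not compared.

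The tests were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. With the levels of early and late heart and the spread fitted over all stage libraries, edgeR recovered 50% and 82%. Of its calls 5.71% were false (DESeq2 18.1%). With the levels of 5 and 0.1 ng and the spread fitted over all input libraries, edgeR recovered 20% and 51%, with 7.79% false (DESeq2 31.3%). Camera called a raised list in both and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other, so this does not cover lists whose genes vary together. The simulated spread was shared by the groups, as the main fit assumes. The shares of false calls therefore do not cover pairs of groups whose own spread differs from the shared one.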

Results

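Transcripts were measured in embryos of the thale cress Arabidopsis thaliana, accession Col-0, at 8 stages of seed development, with 3 biological replicates each. The stages run from preglobular, globular, early heart, late heart, early torpedo and late torpedo to bent cotyledon and mature green, the names following the shape of the embryo. At mature green the titles number 3 replicates while the descriptions call each of them the first. They were taken as 3, and if they came from 1 collection of embryos, SD and tests at that stage leave out the spread between collections. These 24 libraries were made with Smart-seq2, which copies polyadenylated RNA into full-length cDNA and amplifies it. They held between 8432892 and 35807605 estimated read counts each, and at least 17769463 outside the bent-cotyledon stage. Bent-cotyledon RNA was also used to compare inputs and preparation methods. Smart-seq2 was run on 5, 1, 0.5 and 0.1 ng of RNA from 3 replicates, with 1021484 to 11448695 counts per library under 5 ng. Ovation and SMARTer, commercial kits for small amounts of RNA, had 1 library at each of 5, 1, 0.5, 0.1 and 0.05 ng and so no replicates. Their libraries held 3825129 to 8537889 and 2325110 to 11870863 counts. Levels are CPM, read counts relative to the scaled library total, given as mean ± SD over 3 libraries. Adjusted p-values are from edgeR quasi-likelihood tests with Benjamini-Hochberg correction over 21014 tested genes, or from camera where a gene list is tested.

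From the preglobular to the globular stage, the first step, most heat shock genes fell, most nuclear photosynthesis genes rose and embryo patterning genes went both ways. GRF5 (AT3G13960), a transcription factor that promotes leaf cell division, rose from 0.528 ± 0.729 to 52.8 ± 11.02 CPM (SD, n = 3; log2 fold change 6.62, SE 0.49, adjusted p = 1.54e-08). IAMT1 (AT5G55250), which methylates auxin, rose 38.6-fold to 83.3 ± 23.6 CPM. The water channel gene PIP2;8 (AT2G16850) rose 24.5-fold, from 2.40 ± 3.17 to 58.8 ± 7.54 CPM. Preglobular replicate 1 carries its starting mean, at 6.03 CPM against 0.987 and 0.187 in replicates 2 and 3, so the fold is higher without that library. The small heat shock gene HSP17.6A (AT5G12030) fell from 50.4 ± 27.9 to 1.701 ± 1.41 CPM (log2 fold change −4.98, SE 0.80, adjusted p = 0.00014). LCR68 (AT2G02130), of the plant defensins, fell from 1057 ± 457 to 71.4 ± 26.4 CPM, and COBL6 (AT1G09790), of a family of cell wall proteins, from 134 ± 56.5 to 10.04 ± 4.35 CPM. Among embryo patterning genes 11 of 44 measured members rose, 16 fell and 17 did not pass (14 rose and 19 fell adjusted over the list alone). The meristem gene STM (AT1G62360) went from no counts to 7.34 ± 1.66 CPM, at least 161-fold higher, and the root gene TMO7 (AT1G74500) rose 124-fold to 9.32 ± 2.31 CPM. ANT (AT4G37750), of organ growth, rose from 0.181 ± 0.314 to 16.96 ± 6.27 CPM, and CUC1 (AT3G15170), which sets organ boundaries, from 2.64 ± 2.78 to 46.8 ± 9.37 CPM. WOX8 (AT5G45980), a gene of the basal lineage, fell from 38.5 ± 14.6 to 4.32 ± 1.06 CPM, and CNA (AT1G52150), a class III homeodomain gene, from 65.3 ± 17.2 to 12.9 ± 2.88 CPM.

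Also at this step, 7 of 8 measured heat shock genes fell, 0 rose and 1 did not pass, and 7 fell adjusted over the list alone. HSP70 (AT3G12580), a chaperone, fell from 164 ± 26.4 to 21.7 ± 8.96 CPM, and HSFA2 (AT2G26150), a regulator of the heat response, from 97.0 ± 6.30 to 20.07 ± 2.78 CPM. That list ranked below other genes (camera adjusted p = 2.3e-07 with the preset correlation, adjusted p = 0.076 with an estimated correlation). Nuclear photosynthesis genes moved the other way, with 31 of 43 rising, 0 falling and 12 not passing (36 rose adjusted over the list alone; camera adjusted p = 2.1e-15, adjusted p = 0.71 with an estimated correlation). RCA (AT2G39730), which activates Rubisco, rose from 8.30 ± 3.91 to 48.0 ± 11.9 CPM, and GAPB (AT1G42970), of the Calvin cycle, from 5.22 ± 3.69 to 30.9 ± 12.4 CPM. Mitochondrion-encoded genes fell in 78 of 121 cases, 0 rose and 43 did not pass (88 fell adjusted over the list alone; camera adjusted p = 6.6e-21, adjusted p = 0.30 with an estimated correlation). Without preglobular replicate 3, 20 photosynthesis genes rose and 48 mitochondrion-encoded genes fell, and 47 of the latter fell without globular replicate 1. None of 14 DNA replication genes or 22 mitosis genes was called by edgeR, nor adjusted over each list alone. Of 14 maturation regulators ABI3 (AT3G24650) rose from 29.9 ± 5.08 to 70.5 ± 9.84 CPM, while LEC2 (AT1G28300) fell from 30.0 ± 3.75 to 13.3 ± 0.667 CPM and NF-YB6 (AT5G47670) from 21.3 ± 6.28 to 6.77 ± 1.14 CPM. In all, 4961 genes changed, 2406 higher and 2555 lower at the globular stage. On log2(TPM + 1) limma called 8499 higher and 957 lower, a scaling that moves the median of all tested genes by 0.39 on the log2 scale.

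From the globular to the early heart stage, when the cotyledons begin to grow out, most oil body genes rose. LCR69 (AT2G02100), of the defensin family, rose from 4.43 ± 3.57 to 73.7 ± 15.4 CPM (SD, n = 3; 16.6-fold, adjusted p = 0.000121). The oleosin OLEO3 (AT5G51210), a coat protein of oil bodies, rose 10.9-fold to 142 ± 85.3 CPM, and LHCB1.2 (AT1G29910), a light-harvesting protein, 8.23-fold to 111 ± 59.8 CPM. LCR68 fell further, from 71.4 ± 26.4 to 4.29 ± 1.84 CPM, and the lipid transfer protein gene LTP3 (AT5G59320) fell from 2947 ± 855 to 450.3 ± 236 CPM (log2 fold change −2.71, SE 0.27, adjusted p = 3.97e-06). LCR48 (AT3G48231), which encodes a small secreted peptide, fell 3.66-fold, to 16.4 ± 3.98 CPM; its call was lost with limma on log2(TPM + 0.1), at adjusted p = 0.057. Of 7 measured oil body genes 5 rose, 0 fell and 2 did not pass (5 rose adjusted over the list alone; camera adjusted p = 0.00061, adjusted p = 0.58 with an estimated correlation). OLEO2 (AT5G40420) rose from 2.01 ± 1.59 to 47.7 ± 30.3 CPM and OLEO4 (AT3G27660) from 0.641 ± 0.516 to 11.1 ± 7.76 CPM. In fatty acid and oil synthesis 6 of 22 genes rose, 0 fell (1 without globular replicate 2) and 16 did not pass (8 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.58 with an estimated correlation). These included TAG1 (AT2G19450), which makes triacylglycerol, from 43.6 ± 4.47 to 72.7 ± 3.80 CPM, and ROD1 (AT3G15820), which feeds polyunsaturated fatty acids into oil, from 8.74 ± 0.836 to 23.4 ± 7.501 CPM.

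Photosynthesis genes rose in 17 of 43 cases at this step, with 0 falling and 26 not passing (32 rose adjusted over the list alone; camera adjusted p = 3.2e-08, adjusted p = 0.73 with an estimated correlation). Patterning genes went both ways, with 11 rising, 6 falling and 27 not passing (13 and 8 adjusted over the list alone). The leaf gene AS1 (AT2G37630) rose from 25.4 ± 10.4 to 100.0 ± 8.85 CPM, ANT to 86.35 ± 15.3 CPM and STM to 22.8 ± 2.85 CPM. DRN (AT1G12980), which acts in cotyledon formation, fell from 22.9 ± 6.41 to 3.45 ± 3.02 CPM, and WOX2 (AT5G59340), a regulator of the apical lineage, from 22.4 ± 7.11 to 9.95 ± 1.699 CPM, a call lost with limma on log2(TPM + 0.1) at adjusted p = 0.0608. The DNA demethylase gene ROS1 (AT2G36490) rose from 49.4 ± 5.58 to 95.6 ± 11.5 CPM and the silencing gene AGO4 (AT2G27040) from 328 ± 21.6 to 464 ± 24.8 CPM. Without early heart replicates 2 and 3 in turn 5 and 4 photosynthesis genes rose, and 4, 11 and 8 without globular replicates 1, 2 and 3. Without early heart replicate 3, 7 patterning genes rose and 4 fell. Genes in common use as reference genes ranked below others (camera adjusted p = 0.017, adjusted p = 0.58 with an estimated correlation), with 1 of 11 falling, 0 rising and 10 not passing (0 falling without early heart replicate 3 or globular replicate 3, 2 without globular replicate 2). In total 3698 genes changed, 1801 higher and 1897 lower, and the count was 2038 without early heart replicate 2, 1837 without early heart replicate 3 and 2210 without globular replicate 1. Limma on log2(TPM + 1) called 4836 higher and 746 lower, with a median shift of 0.27.

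Between early and late heart, fewer genes changed, and the patterning gene DRN and the lipid transfer gene LTP3 continued to fall. LHCB2.2 (AT2G05070), a light-harvesting protein, rose from 7.58 ± 4.25 to 57.9 ± 4.19 CPM (SD, n = 3; log2 fold change 2.93, SE 0.65, adjusted p = 0.0161), YAB3 (AT4G00180), a regulator of the lower leaf side, from 9.87 ± 8.22 to 53.4 ± 1.16 CPM, and the homeodomain gene HB33 (AT1G75240) from 14.2 ± 9.70 to 54.7 ± 6.81 CPM. LTP3 fell from 450.3 ± 236 to 37.7 ± 2.93 CPM (log2 fold change −3.58, SE 0.28, adjusted p = 8.49e-07), and GDH1 (AT5G18170), for glutamate dehydrogenase, from 132 ± 23.7 to 50.4 ± 3.03 CPM. SHP1 (AT3G58780), a MADS-box gene of ovule and carpel, fell from 85.9 ± 24.7 to 30.9 ± 5.71 CPM. Among patterning genes 7 of 44 fell, 1 rose and 36 did not pass (12 fell and 1 rose adjusted over the list alone; camera adjusted p = 8.8e-05, adjusted p = 0.22 with an estimated correlation). DRN fell from 3.45 ± 3.02 to 0.127 ± 0.0559 CPM, and the member that rose was WOX1 (AT3G18010), of leaf blade growth, from 1.00 ± 0.271 to 3.39 ± 0.530 CPM. AGO9 (AT5G21150), an Argonaute of gene silencing, fell from 107 ± 32.7 to 41.4 ± 12.1 CPM. Plastid-encoded genes rose in 15 of 130 cases, 0 fell and 115 did not pass (65 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.3e-36, adjusted p = 0.11 with an estimated correlation). For fatty acid synthesis genes 1 of 22 rose, 0 fell and 21 did not pass, against 10 adjusted over the list alone (camera adjusted p = 7.3e-11, adjusted p = 0.11 with an estimated correlation; fry, which tests whether a list moves one way on balance, adjusted p = 0.014). Of 10 endosperm genes 1 fell, 0 rose and 9 did not pass, and 3 fell adjusted over the list alone (camera adjusted p = 5e-04, adjusted p = 0.11 with an estimated correlation).

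The step from early to late heart, with patterning genes, LHCB2.2 and LTP3 among its changes, gave 515 changed genes, 256 higher and 259 lower. Several calls rested on single libraries. The count was 180 without early heart replicate 1, 340 without early heart replicate 2, 281 without late heart replicate 1, 243 without late heart replicate 2 and 170 without late heart replicate 3. LHCB2.2 did not pass without early heart replicate 1 (adjusted p = 0.121), late heart replicate 2 (adjusted p = 0.0515) or late heart replicate 3 (adjusted p = 0.053). YAB3 was lost without late heart replicates 1, 2 and 3 in turn (adjusted p = 0.055, 0.055 and 0.0681) and in a fit of these 6 libraries alone (adjusted p = 0.0557). HB33 was lost without late heart replicate 3 (adjusted p = 0.0567). SHP1 was lost without early heart replicate 1 or 2 (adjusted p = 0.116 and 0.108) and without late heart replicates 1, 2 and 3 in turn (adjusted p = 0.059, 0.141 and 0.109). LTP3, GDH1, DRN, WOX1 and AGO9 passed without each of the 6 libraries in turn. Of patterning genes 1 fell without early heart replicate 1 and 2 without each late heart replicate in turn. Of plastid-encoded genes 3 and 4 rose without early heart replicates 1 and 2, and 8, 4 and 1 without late heart replicates 1, 2 and 3. The fall of the endosperm gene was lost without each of the 6 libraries, and the rise of the fatty acid gene without each but early heart replicate 3. Limma on log2(TPM + 1) called 271 higher and 461 lower.

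**Figure D1:**
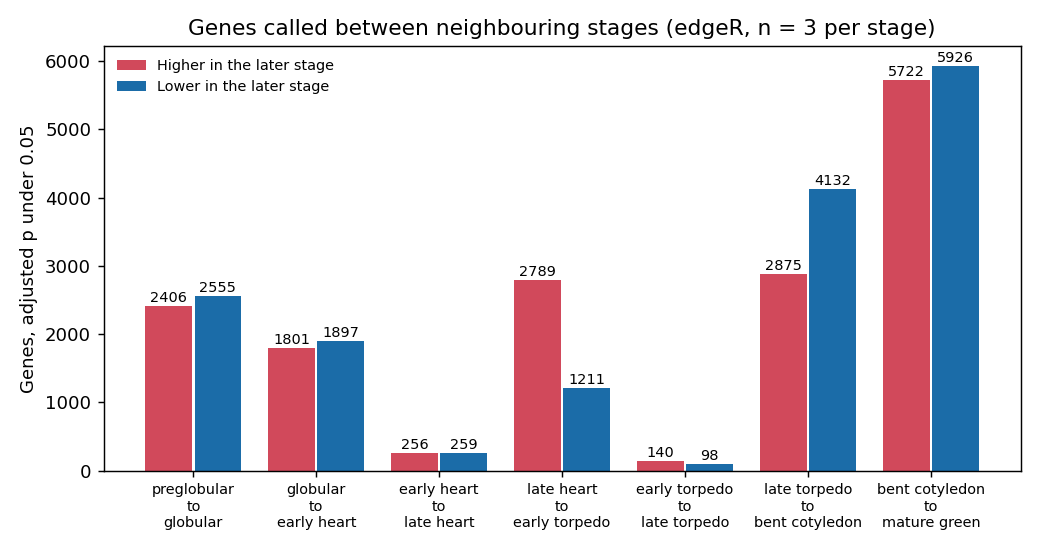
Genes called higher and lower at the later stage (edgeR, adjusted over 21014 tested genes), as bars side by side for each of the 7 neighbouring pairs of stages. The bars are longest from bent cotyledon to mature green, with 5722 genes higher and 5926 lower, and shortest from early to late torpedo, with 140 and 98.

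From late heart to early torpedo, most seed storage, oil body and fatty acid synthesis genes rose with all libraries in the fit. COR47 (AT1G20440), a dehydrin of cold and drought, rose from 6.23 ± 2.03 to 54.4 ± 16.4 CPM (SD, n = 3; log2 fold change 3.13, SE 0.49, adjusted p = 0.000348). The Rubisco subunit gene RBCS3B (AT5G38410) rose from 21.98 ± 2.07 to 215 ± 260.1 CPM and LHCB2.3 (AT3G27690) from 14.6 ± 1.00 to 134 ± 156 CPM, at 65.4 and 44.2 CPM without early torpedo replicate 2, which carries both means. ERL2 (AT5G07180) and ERL1 (AT5G62230), receptor kinases that pattern stomata, fell from 168 ± 25.9 to 67.3 ± 24.2 CPM and from 101 ± 10.97 to 43.7 ± 15.6 CPM, and DIC2 (AT4G24570), a mitochondrial carrier, fell from 50.8 ± 9.58 to 18.8 ± 6.95 CPM. Of 9 storage protein genes 7 rose, 0 fell and 2 did not pass (8 rose adjusted over the list alone; camera adjusted p = 2.9e-05, adjusted p = 0.28 with an estimated correlation). SESA3 (AT4G27160), an albumin, rose from 0.342 ± 0.149 to 18.4 ± 11.03 CPM (12.2 without early torpedo replicate 2). In fatty acid and oil synthesis 17 of 22 genes rose, 0 fell (1 without early torpedo replicate 1) and 5 did not pass (17 rose and 1 fell adjusted over the list alone; camera adjusted p = 5.4e-09, adjusted p = 0.28 with an estimated correlation). KCS18 (AT4G34520), which lengthens fatty acids for seed oil, rose 139.6-fold to 13.0 ± 8.26 CPM (8.25 without the same library), ROD1 rose from 46.1 ± 6.67 to 156 ± 46.5 CPM, and KASI (AT5G46290), of fatty acid chain building, from 503 ± 20.9 to 910.2 ± 180.3 CPM. Oil body genes rose in 5 of 7 cases, 0 fell and 2 did not pass (6 rose adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.33 with an estimated correlation), OLEO1 (AT4G25140) going from 13.5 ± 6.27 to 112 ± 35.2 CPM. Without early torpedo replicate 2, which stood apart from its stage, 4 storage protein and 2 oil body genes rose. Without late heart replicate 1 or 2 it was 2 oil body genes and 10 of fatty acid synthesis.

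Photosynthesis genes rose in 18 of 43 cases here, 0 fell and 25 did not pass (33 rose adjusted over the list alone; camera adjusted p = 3.7e-07, adjusted p = 0.57 with an estimated correlation). Plastid-encoded genes rose in 42 of 130 cases, 0 fell and 88 did not pass (51 rose adjusted over the list alone; camera adjusted p = 8.5e-09, adjusted p = 0.53 with an estimated correlation). DNA methylation and silencing genes fell in 15 of 27 cases, 0 rose and 12 did not pass (19 fell and 1 rose adjusted over the list alone; camera adjusted p = 8.5e-09, adjusted p = 0.28 with an estimated correlation). AGO9 fell from 41.4 ± 12.1 to 9.88 ± 3.26 CPM and AGO5 (AT2G27880), of the same family, from 9.89 ± 3.89 to 2.44 ± 0.310 CPM. Among patterning genes 13 fell, 2 rose and 29 did not pass (14 and 2 adjusted over the list alone; camera adjusted p = 2.3e-05, adjusted p = 0.28 with an estimated correlation), with the boundary gene CUC2 (AT5G53950) falling from 9.74 ± 0.898 to 2.32 ± 0.998 CPM. Replication genes fell in 5 of 14 cases, 0 rose and 9 did not pass (9 fell adjusted over the list alone; camera adjusted p = 0.00022, adjusted p = 0.44 with an estimated correlation). Without early torpedo replicate 2, 2 photosynthesis and 12 plastid-encoded genes rose, and 7 silencing and 0 replication genes fell. Without late heart replicates 1, 2 and 3 in turn 4, 3 and 4 photosynthesis and 11, 14 and 25 plastid-encoded genes rose, and 0, 0 and 3 replication genes fell. Silencing genes that fell were 6 and 7 without late heart replicates 1 and 2, and patterning genes that fell were 6 and 8. The 2 patterning genes that rose became 1 or 0 without any of these 6 libraries. The mitotic cyclin gene CYCB1;3 (AT3G11520) fell from 82.8 ± 5.64 to 47.3 ± 5.60 CPM. Of the maturation regulators NF-YB6, a relative of LEC1 (AT1G21970), rose from 25.6 ± 6.61 to 162 ± 28.5 CPM. EdgeR called 4000 genes, 2789 higher and 1211 lower, and 1945 without early torpedo replicate 2, 1280 without late heart replicate 1 and 1723 without late heart replicate 2. Limma on log2(TPM + 1) gave the opposite balance, 923 higher and 8137 lower, with the median of all tested genes moved by −0.36. The silencing, patterning, photosynthesis, storage and oil lists kept their direction on that scale.

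Between early and late torpedo the seed storage genes rose. SESA3 rose from 18.4 ± 11.03 to 239 ± 56.5 CPM (SD, n = 3; log2 fold change 3.70, SE 0.58, adjusted p = 0.00231). The albumin SESA2 (AT4G27150) rose from 8.42 ± 13.7 to 285 ± 216 CPM (adjusted p = 0.0186) and the cruciferin CRA1 (AT5G44120) from 41.5 ± 58.8 to 398 ± 155 CPM (adjusted p = 0.0415). Without early torpedo replicate 2 the early torpedo means of SESA3, SESA2 and CRA1 were 12.2, 0.530 and 7.61 CPM, and without late torpedo replicate 3 SESA2 stood at 160.6 CPM at late torpedo. PCK1 (AT4G37870), which turns oxaloacetate into sugar precursors, fell from 111 ± 28.6 to 30.2 ± 9.14 CPM (log2 fold change −1.88, SE 0.23, adjusted p = 0.000232). The defence regulator WRKY17 (AT2G24570) fell from 101 ± 3.18 to 60.5 ± 4.47 CPM and the chaperone Hsp70-2 (AT5G02490) from 182 ± 30.8 to 110.4 ± 6.71 CPM. All 9 storage protein genes rose, over all genes and adjusted over the list alone, and camera ranked the list above other genes with the preset (adjusted p = 1.7e-27) and with an estimated correlation (adjusted p = 0.0021). CRU2 (AT1G03880), a cruciferin, rose from 0.522 ± 0.648 to 23.2 ± 7.79 CPM, and the albumin SESA4 (AT4G27170) from 0.773 ± 0.967 to 23.8 ± 4.21 CPM. Oil body genes rose in 2 of 7 cases, 0 fell and 5 did not pass (5 rose adjusted over the list alone; camera adjusted p = 1.4e-06, adjusted p = 0.13 with an estimated correlation), among them CLO1 (AT4G26740), a caleosin, from 0.812 ± 0.242 to 9.29 ± 6.02 CPM (5.82 without late torpedo replicate 3). Among patterning genes 7 fell, 0 rose and 37 did not pass (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.51 with an estimated correlation). They included the auxin exporter PIN4 (AT2G01420), from 38.4 ± 7.75 to 10.01 ± 2.68 CPM, and the root stem cell gene PLT2 (AT1G51190), from 23.1 ± 8.49 to 7.69 ± 3.40 CPM. Patterning genes that fell were 3 and 2 without early torpedo replicates 1 and 3, and 4 and 1 without late torpedo replicates 2 and 3. Oil body genes that rose were 1, 4 and 1 without early torpedo replicates 1, 2 and 3 in turn, and 1 without late torpedo replicate 3.

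The torpedo step gave the smallest count among the stage pairs, 238 genes, 140 higher and 98 lower, and it depended on single libraries. The count was 1154 without early torpedo replicate 2, 53 without early torpedo replicate 1, 64 without early torpedo replicate 3, 116 without late torpedo replicate 1 and 44 without late torpedo replicate 3. In a fit of these 6 libraries alone 3 genes passed, and SESA3, PCK1, PIN4, CRU2, SESA4 and CLO1 each had adjusted p = 0.0748. Those 6 genes passed without each library in turn. The other genes named at this step were not called in the fit of 6 libraries either. Their edgeR adjusted p was 0.0748 for WRKY17, 0.126 for Hsp70-2, 0.159 for PLT2, 0.232 for SESA2 and 0.292 for CRA1. SESA2 did not pass without early torpedo replicate 1 (adjusted p = 0.0763), early torpedo replicate 3 (adjusted p = 0.0831) or late torpedo replicate 3 (adjusted p = 0.104). CRA1 was lost without early torpedo replicate 1 or 3 (adjusted p = 0.171 and 0.0914) and without late torpedo replicates 1, 2 and 3 in turn (adjusted p = 0.0708, 0.0597 and 0.18). WRKY17 was lost without early torpedo replicate 1 or 3 (adjusted p = 0.0792 and 0.0566) and without late torpedo replicate 3 (adjusted p = 0.119). Hsp70-2 was lost without early torpedo replicate 1 (adjusted p = 0.174) and without late torpedo replicates 1, 2 and 3 in turn (adjusted p = 0.128, 0.0757 and 0.12), and PLT2 without late torpedo replicate 3 (adjusted p = 0.0562).

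At the bent-cotyledon stage, after late torpedo, most storage protein, oil body and fatty acid synthesis genes rose. CRU3 (AT4G28520), a cruciferin, rose from 12.9 ± 6.29 to 999 ± 22.8 CPM (SD, n = 3; log2 fold change 6.28, SE 0.36, adjusted p = 2.36e-09), and PER1 (AT1G48130), a seed peroxiredoxin, rose 68.2-fold to 73.9 ± 6.56 CPM. DIR1 (AT5G48485), a lipid transfer protein of systemic defence, went from no counts at late torpedo to 100.3 ± 23.4 CPM, at least 1821-fold higher, though it lies beside a paralog with which reads may be shared, and DESeq2 did not call it (adjusted p = 0.0634). RGP3 (AT3G08900), an enzyme of arabinose supply to the cell wall, fell from 75.5 ± 8.42 to 7.10 ± 1.99 CPM, the protease gene DEG14 (AT5G27660) from 242 ± 32.7 to 27.6 ± 0.849 CPM and NOP10 (AT2G20490), a protein of ribosomal RNA modification, from 188 ± 33.4 to 40.6 ± 4.37 CPM. In fatty acid and oil synthesis 18 of 22 genes rose, 0 fell and 4 did not pass, as they did adjusted over the list alone (camera adjusted p = 6.4e-09, adjusted p = 0.31 with an estimated correlation). FAD3 (AT2G29980), which makes linolenic acid, rose from 172 ± 17.39 to 552 ± 137 CPM and WRI1 (AT3G54320), which switches on fatty acid synthesis, from 128 ± 7.11 to 278 ± 80.3 CPM. Storage protein genes rose in 7 of 9 cases, 0 fell and 2 did not pass (8 rose adjusted over the list alone; camera adjusted p = 4.4e-06, adjusted p = 0.31 with an estimated correlation). Oil body genes rose in 6 of 7 cases, 0 fell and 1 did not pass (7 rose adjusted over the list alone; camera adjusted p = 0.00026, adjusted p = 0.31 with an estimated correlation), with OLEO1 at 3878 ± 819 CPM. Of 14 maturation regulators 6 rose, 2 fell and 6 did not pass (6 and 3 adjusted over the list alone), DOG1 (AT5G45830), a dormancy gene, rising from 0.442 ± 0.168 to 6.79 ± 1.49 CPM and LEC1 falling from 122 ± 24.4 to 33.0 ± 0.0880 CPM.

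Wound and handling genes rose in 7 of 16 cases at the same step, 0 fell and 9 did not pass (7 rose adjusted over the list alone; camera adjusted p = 0.00026, adjusted p = 0.34 with an estimated correlation). Of these 3 rose without bent cotyledon replicate 1 or late torpedo replicate 1, and 4 without bent cotyledon replicate 2 or late torpedo replicate 2. The jasmonate repressor JAZ1 (AT1G19180) rose from 17.7 ± 6.78 to 51.5 ± 11.9 CPM and the touch gene TCH4 (AT5G57560) from 87.4 ± 43.3 to 245 ± 28.2 CPM. Silencing genes rose in 10 of 27 cases, 1 fell and 16 did not pass (10 and 2 adjusted over the list alone; camera adjusted p = 0.033, adjusted p = 0.73 with an estimated correlation), with the demethylase genes DME (AT5G04560) and ROS1 rising from 21.1 ± 4.45 to 44.6 ± 2.27 CPM and from 89.1 ± 20.6 to 184 ± 8.71 CPM. Of 20 measured seed coat genes 6 rose, 4 fell and 10 did not pass (6 and 5 adjusted over the list alone). The flavonoid genes TT4 (AT5G13930) and TT7 (AT5G07990) rose from 41.7 ± 13.0 to 409 ± 174 CPM and from 5.24 ± 1.19 to 108 ± 54.3 CPM, while BAN (AT1G61720), of tannin synthesis, fell from 2.48 ± 0.132 to 0.139 ± 0.128 CPM. Endosperm genes fell in 5 of 10 cases, 0 rose and 5 did not pass, as they did adjusted over the list alone, ALE1 (AT1G62340) from 4.65 ± 0.352 to 0.274 ± 0.0425 CPM, and 3 fell without bent cotyledon replicate 2 or 3. In the silencing list 0 fell without bent cotyledon replicate 2, and 7 rose and 2 fell without late torpedo replicate 1. Mitosis genes fell in 5 of 22 cases, 0 rose (1 without late torpedo replicate 2) and 17 did not pass, and of the reference genes UBC21 (AT5G25760), for ubiquitin transfer, fell from 37.0 ± 1.61 to 19.1 ± 2.52 CPM. EdgeR called 7007 genes at this step, 2875 higher and 4132 lower.

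From bent cotyledon to mature green, the last step, storage protein and most LEA genes rose, while cell division genes and most photosynthesis genes fell. EM1 (AT3G51810), a late embryogenesis abundant (LEA) protein of desiccation tolerance, went from no counts to 716 ± 833 CPM (SD, n = 3), at least 7013-fold higher (adjusted p = 8.18e-07). GASA2 (AT4G09610), of a gibberellin-regulated peptide family, went from no counts to 258 ± 320.3 CPM, at least 2521-fold, and GASA3 (AT4G09600) rose 53779-fold to 1873 ± 1523 CPM (95% counting interval 9652 to 2124173, on 1 to 3 counts at bent cotyledon). Mature green replicate 3 carries these means, which were 236 CPM for EM1, 72.6 for GASA2 and 994 for GASA3 without it, so the folds are lower without that library. DIR1 and the jasmonate regulator MYC2 (AT1G32640) had no counts at mature green, at least 1263-fold and 644-fold lower, and RBCS3B fell 639-fold, from 239 ± 13.6 to 0.373 ± 0.110 CPM (adjusted p = 1.49e-07). DESeq2 did not call the fall of DIR1 (adjusted p = 0.0551). All 9 storage protein genes rose, over all genes and adjusted over the list alone (camera adjusted p = 7.3e-06, adjusted p = 0.17 with an estimated correlation). CRU3 rose from 999 ± 22.8 to 88068 ± 5806 CPM and SESA3 from 4839.7 ± 116 to 186213 ± 28462 CPM. LEA genes rose in 14 of 15 cases, 1 fell and 0 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 3.4e-06, adjusted p = 0.17 with an estimated correlation). RAB18 (AT5G66400), a dehydrin, rose from 0.782 ± 0.253 to 339 ± 370.0 CPM (127 without mature green replicate 3) and ECP63 (AT2G36640) from 3.49 ± 0.909 to 238 ± 133 CPM. In the metabolism of abscisic acid and gibberellin, hormones of dormancy and germination, 5 of 7 genes rose, 0 fell and 2 did not pass (6 rose adjusted over the list alone; camera adjusted p = 0.0098, adjusted p = 0.12 with an estimated correlation). NCED9 (AT1G78390), of abscisic acid synthesis, rose from 1.23 ± 1.01 to 109 ± 48.7 CPM, and the dormancy gene DOG1 from 6.79 ± 1.49 to 444 ± 158 CPM.

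All 14 DNA replication genes and all 22 mitosis genes fell at this last step, over all genes and adjusted over each list alone (camera adjusted p = 1e-10 and 8.2e-15, adjusted p = 0.12 for both with an estimated correlation). PCNA1 (AT1G07370), the sliding clamp of replication, fell from 52.8 ± 4.26 to 0.545 ± 0.344 CPM, and KN (AT1G08560), which closes the cell plate at division, from 219 ± 7.62 to 2.21 ± 2.01 CPM. Photosynthesis genes fell in 40 of 43 cases, 0 rose and 3 did not pass (42 fell adjusted over the list alone; camera adjusted p = 3.5e-09, adjusted p = 0.44 with an estimated correlation), LHCB2.2 from 770.3 ± 47.8 to 8.50 ± 6.70 CPM (5.52 without mature green replicate 2). Plastid-encoded genes fell in 116 of 130 cases, 1 rose and 13 did not pass (117 and 1 adjusted over the list alone; camera adjusted p = 4.4e-21, adjusted p = 0.20 with an estimated correlation). Silencing genes fell in 17 of 27 cases, 3 rose and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.44 with an estimated correlation). The DNA methyltransferase genes CMT3 (AT1G69770) and MET1 (AT5G49160) fell from 34.3 ± 3.92 to 1.51 ± 0.758 CPM and from 36.7 ± 5.74 to 4.44 ± 1.17 CPM. Fatty acid and oil synthesis genes parted, 4 rising, 13 falling and 5 not passing, with the same counts adjusted over the list alone. FAD3 rose from 552 ± 137 to 6709 ± 262 CPM, while KASI fell from 1678 ± 23.7 to 508 ± 102 CPM. Patterning genes fell in 20 of 44 cases, 2 rose and 22 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.0029, adjusted p = 0.32 with an estimated correlation), and the auxin response gene MP (AT1G19850) fell 11.3-fold to 5.71 ± 1.59 CPM. The 2 that rose were 1 and 0 without bent cotyledon replicates 2 and 3, and 1 and 4 without mature green replicates 2 and 3. The reference gene ACT2 (AT3G18780), an actin, fell from 227 ± 1.31 to 39.2 ± 10.9 CPM. EdgeR called 11648 genes, 5722 higher and 5926 lower, and limma on log2(TPM + 1) 2437 higher and 10404 lower, with the median of all tested genes moved by −0.51.

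**Figure D2:**
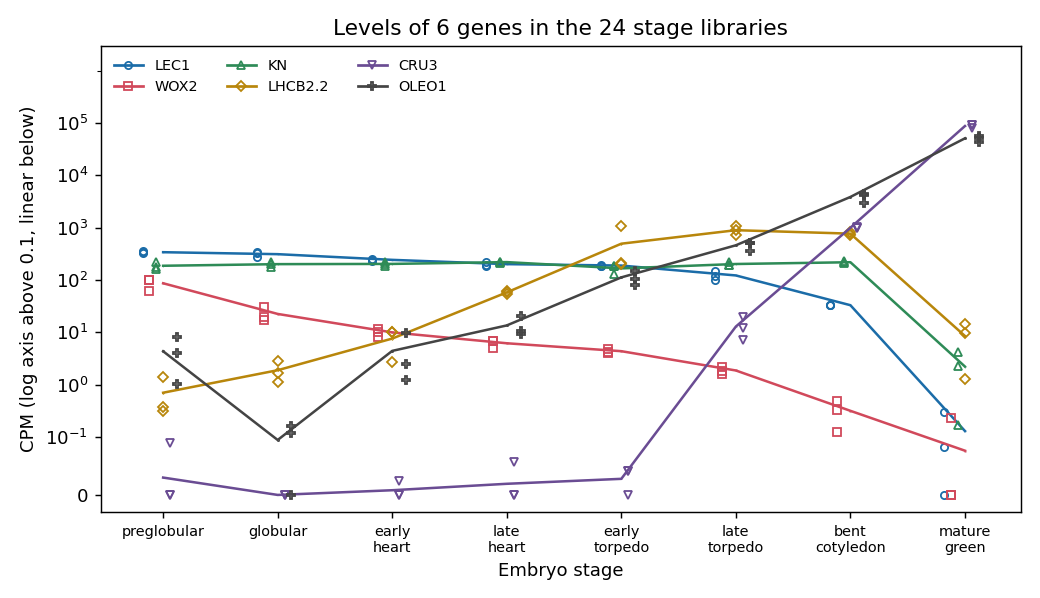
CPM in each of the 24 stage libraries (points) and stage means (lines) of LEC1, WOX2, KN, LHCB2.2, CRU3 and OLEO1; the axis is logarithmic above 0.1 CPM and linear below. CRU3 and OLEO1 reached 88068 and 51256 CPM at mature green, where LEC1 and WOX2 were at 0.129 and 0.0761 CPM.

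Over the whole series, from preglobular to mature green, most of the largest rises named by the rule were of seed reserve genes, and the falls were of mixed function, from lipid transfer to embryo regulators. SESA1 (AT4G27140), KCS18, ATPXG2 (AT5G55240), E12A11 (AT1G18100) and EM1 had no counts at the preglobular stage. They reached 11187 ± 4585, 1547 ± 152, 1459 ± 328, 750.0 ± 103 and 716 ± 833 CPM (SD, n = 3), at least 244995-fold, 33884-fold, 31951-fold, 16426-fold and 15689-fold higher; without mature green replicate 3 the mean of EM1 was 236 CPM. ATPXG2 encodes a peroxygenase of oil bodies and E12A11 a relative of the flowering protein FT. CRU2, CRU3 and CRA1 had 1 to 3 counts at the preglobular stage and rose 5519728-fold, 2891471-fold and 1241737-fold, with 95% counting intervals of 990682 to 218017986, 800441 to 23875813 and 424899 to 6021312. SESA2 rose 191219.6-fold, from 0.332 ± 0.352 to 63516 ± 3289.9 CPM, and SESA4 176249-fold, from 0.633 ± 0.589 to 111553 ± 12254 CPM. Their preglobular levels were 0.73 and 1.22 CPM in replicate 1 and 0.047 CPM for both in replicate 3. The folds are therefore higher without preglobular replicate 1. LTP3 fell from 4208 ± 200.2 to 0.183 ± 0.114 CPM (log2 fold change −14.43, SE 0.49, adjusted p = 1.05e-15). LEC1, which keeps cells embryonic, fell from 340.2 ± 16.4 to 0.129 ± 0.157 CPM (log2 fold change −11.27, SE 0.30, adjusted p = 9.98e-17). WOX2 fell 1090.1-fold, to 0.0761 ± 0.132 CPM (95% counting interval 373 to 5288). The zinc finger gene LATE (AT5G48890) fell 2181-fold from 115 ± 2.63 CPM (95% counting interval 604 to 18009.9), LCR48 1036-fold (354 to 5025), ENODL4 (AT4G32490), an early nodulin-like gene, 1505-fold and PAB5 (AT1G71770), for a poly(A)-binding protein, 989.9-fold. SWEET12 (AT5G23660), a sucrose exporter, fell 788-fold from 247 ± 92.4 CPM and COBL6 737-fold, and GAD (AT5G17330), for glutamate decarboxylase, went from 51.6 ± 18.1 CPM to no counts, at least 651-fold lower. Reads of the SESA1, SESA2, SESA3 and SESA4 paralogs can be exchanged between neighbours.

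Across that span 15949 genes changed, 8100 higher and 7849 lower, and 19141 of 21014 varied over the 8 stages. Limma on log2(TPM + 1) called 5252 higher and 9173 lower between the ends, with a median shift of −0.34. Of the reserve lists, 9 of 9 storage, 7 of 7 oil body and 19 of 22 fatty acid synthesis genes rose and 0 fell, and of 15 LEA genes 14 rose and 1 fell, with the same counts adjusted over each list alone. Camera gave these lists adjusted p = 1e-06, 6.1e-05, 1e-06 and 6.3e-06, and adjusted p = 0.14 with an estimated correlation for each. Replication (14 of 14) and mitosis genes (22 of 22) all fell, PCNA1 from 237 ± 9.76 and CYCB1;3 from 125 ± 11.97 CPM (camera adjusted p = 4.2e-07 and 2.9e-09, adjusted p = 0.14 for both with an estimated correlation). Photosynthesis genes rose in 40 of 43 cases, 0 fell (1 without preglobular replicate 3) and 3 did not pass (camera adjusted p = 4.6e-06, adjusted p = 0.51 with an estimated correlation). Among patterning genes 12 rose, 28 fell and 4 did not pass (camera adjusted p = 0.0069, adjusted p = 0.31 with an estimated correlation). In the silencing list 8 rose, 15 fell and 4 did not pass, the maintenance factor VIM1 (AT1G57820) falling from 267 ± 25.3 to 5.96 ± 3.17 CPM. Reference genes fell in 8 of 11 cases, 2 rose (1 without preglobular replicate 1 or mature green replicate 1 or 3) and 1 did not pass, and the initiation factor gene EIF4A1 (AT3G13920) fell from 1578 ± 158 to 333 ± 38.2 CPM. Mitochondrion-encoded genes fell in 100 of 121 cases, 0 rose and 21 did not pass (105 fell adjusted over the list alone; camera adjusted p = 2.1e-08, adjusted p = 0.31 with an estimated correlation). Of the 10 measured endosperm genes 5 fell and 5 did not pass (1 rose without preglobular replicate 1), and of 20 seed coat genes 10 rose, 6 fell and 4 did not pass.

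Shares of all transcripts, in percent of the TPM total, show how far a few gene groups fill the later libraries. Storage protein genes held 3.2e-04% at preglobular, 0.118 ± 0.0585% (SD, n = 3) at late torpedo, 1.2005 ± 0.149% at bent cotyledon and 37.3 ± 1.52% at mature green. Oil body genes went from 0.00392% at preglobular to 7.68 ± 0.394% at mature green. LEA genes held 0.00571% at preglobular and 0.508 ± 0.332% at mature green. Photosynthesis genes rose from 0.0765 ± 0.0449% to 4.76 ± 0.760% at late torpedo and stood at 0.638 ± 0.335% at mature green, and plastid-encoded genes peaked at 13.3 ± 1.47% at bent cotyledon. The 100 most abundant genes took 37.2 ± 1.401% at preglobular, 27.4 ± 0.830% at late heart and 64.0 ± 0.786% at mature green. Shares differed between stages in each of the 19 groups tested (permutation test over 24 libraries), with adjusted p from 1.4e-05 to 0.0064; the smallest p of 1e-05 is the smallest that 100000 permutations can give.

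**Figure D3:**
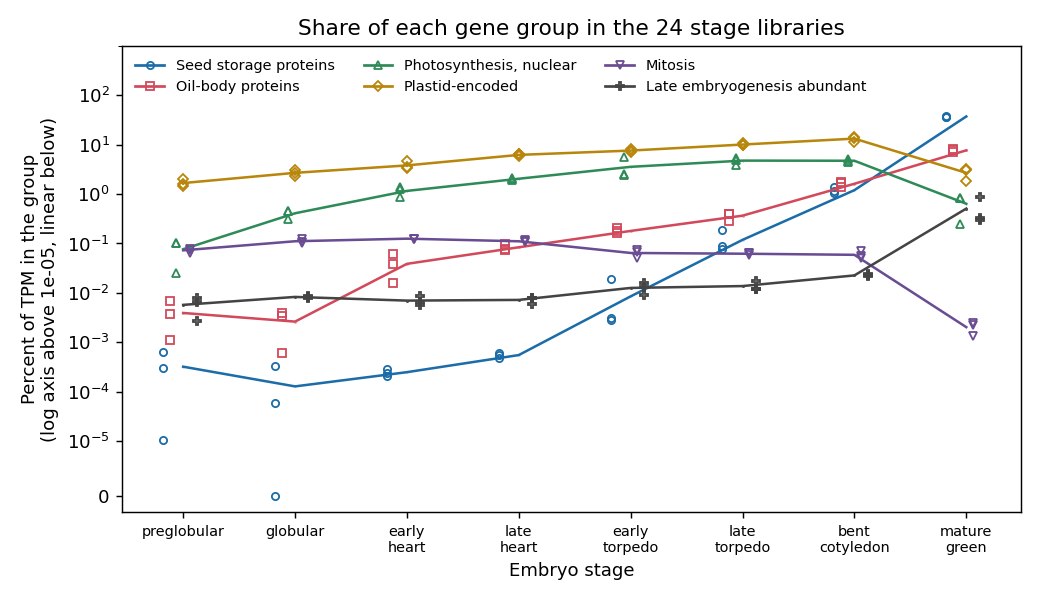
Share of all TPM (percent) held by gene groups in each of the 24 stage libraries; points are libraries, lines are means of 3 and the axis is logarithmic above 1e-05 and linear below. Storage protein genes reach 37.3% at mature green, where photosynthesis genes are at 0.638%.

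The number of genes detected was compared after thinning every stage library at random to 7994611 counts and taking genes with 5 or more. It was 17262 ± 212 (SD, n = 3) at preglobular, 18041 ± 289.8 at early torpedo, 17749 ± 34.6 at bent cotyledon and 16942 ± 229 at mature green. The mean at mature green minus that at bent cotyledon was −807 (exact permutation test, two-sided, p = 0.1, the smallest 3 against 3 libraries allow). By Spearman correlation of log2(TPM + 1) across genes, 21 of 24 libraries were closer to each library of their own stage than to any of another stage. The exceptions were all 3 early torpedo libraries: replicate 1 was closer to a late heart library, and replicates 2 and 3 to a late torpedo library, than to 1 of their own stage. Over all genes with 1 count in any library it was 16 of 24, the exceptions being these 3, preglobular replicates 1 and 3, globular replicates 1 and 2 and late torpedo replicate 1. The first component of log2 CPM took 52.15% of the variance and the second 22.04%. Genes are not independent replicates, so no p-value goes with these.

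**Figure D4:**
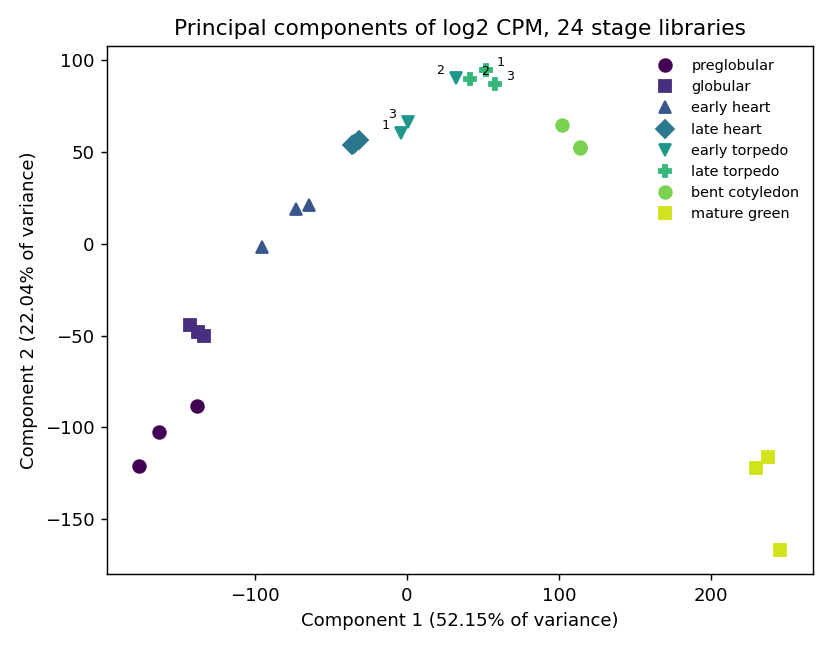
First and second principal component of log2 CPM of the tested genes for the 24 stage libraries, 1 point per library, coloured by stage; they hold 52.15% and 22.04% of the variance. The mature green libraries lie apart from the other stages.

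Dilution of bent-cotyledon RNA in Smart-seq2 addresses how far less RNA changes the levels read for the same genes, from seed storage to patterning. Of the 17090 genes tested, edgeR called none between 5 and 1 ng (11 at an unadjusted p under 0.05; DESeq2 0, limma 0) and none between 5 and 0.5 ng (66 at an unadjusted p under 0.05; DESeq2 1, limma 0). At 0.1 ng 35 genes were called, all lower, in the fit that does not pair libraries of the same RNA. With the replicate block, which pairs them, edgeR called 0 (2069 at an unadjusted p under 0.05), while DESeq2 without the block called 434. The zinc finger gene OXS2 (AT2G41900), which acts in stress responses, met the naming rule and fell from 70.6 ± 6.996 CPM at 5 ng to 37.5 ± 5.13 at 0.1 ng (SD, n = 3; log2 fold change −0.92, SE 0.17, adjusted p = 0.0489). Its call was lost with the replicate block (adjusted p = 0.11), without any of the 5 ng replicates 1, 2 and 3 (adjusted p = 0.157, 0.218 and 0.173) and without 0.1 ng replicate 2 (adjusted p = 0.059), and the settings that lost it gave adjusted p from 0.0555 to 0.642. The count of 35 went to 708, 98 and 530 without 0.1 ng replicates 1, 2 and 3, and to 0 without any 5 ng replicate. No member of the gene lists was called, though up to 3 members of a list were without 0.1 ng replicates 1, 2 and 3 in turn. Photosynthesis genes ranked above other genes at 1, 0.5 and 0.1 ng with the preset correlation (camera adjusted p = 0.0016, 0.0011 and 0.0018), on log2(TPM + 1) only at 0.1 ng (adjusted p = 0.50, 0.98 with the direction turned, and 0.034), and in no case with an estimated correlation (adjusted p = 0.96, 0.92 and 0.94).

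Agreement with the 5 ng profile of the same method, as Pearson r of log2(TPM + 1) across genes, was lower at each lower input in Smart-seq2 and Ovation, while in SMARTer it was lowest at 0.1 ng and higher again at 0.05 ng. For Smart-seq2 r was 0.987 ± 0.00282 at 1 ng, 0.981 ± 0.00507 at 0.5 ng and 0.949 ± 0.0155 at 0.1 ng (SD, n = 3), and replicates at 5 ng had r of 0.984 to 0.988 among themselves. For Ovation r was 0.969, 0.964, 0.937 and 0.909 at 1, 0.5, 0.1 and 0.05 ng, and for SMARTer 0.969, 0.943, 0.767 and 0.834. Of genes at 1 TPM or more at 5 ng, 9.40 ± 3.95% were at 0 in Smart-seq2 at 0.1 ng, 2.47% in Ovation and 48.6% in SMARTer, over 6647 genes in Ovation and 15775 in SMARTer. Over protein-coding genes, a setting chosen after seeing the data, Ovation was not below Smart-seq2, at 12.7% against 10.7 ± 4.05% (48.7% in SMARTer), nor with thinned counts, at 20.7% against 16.99 ± 4.88% (58.9% in SMARTer). After thinning all to 987518 counts, Smart-seq2 detected 13736 ± 108 genes at 5 ng and 12827 ± 518 at 0.1 ng. Ovation detected 7673 at 5 ng and 7353 at 0.1 ng, and SMARTer 12076 and 5893. Thinned on protein-coding genes alone, to 623171 counts, Smart-seq2 detected 12554 ± 54.4 at 5 ng and 11695 ± 336 at 0.1 ng, Ovation 12027 and 10623, and SMARTer 10605 and 5454.

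**Figure D5:**
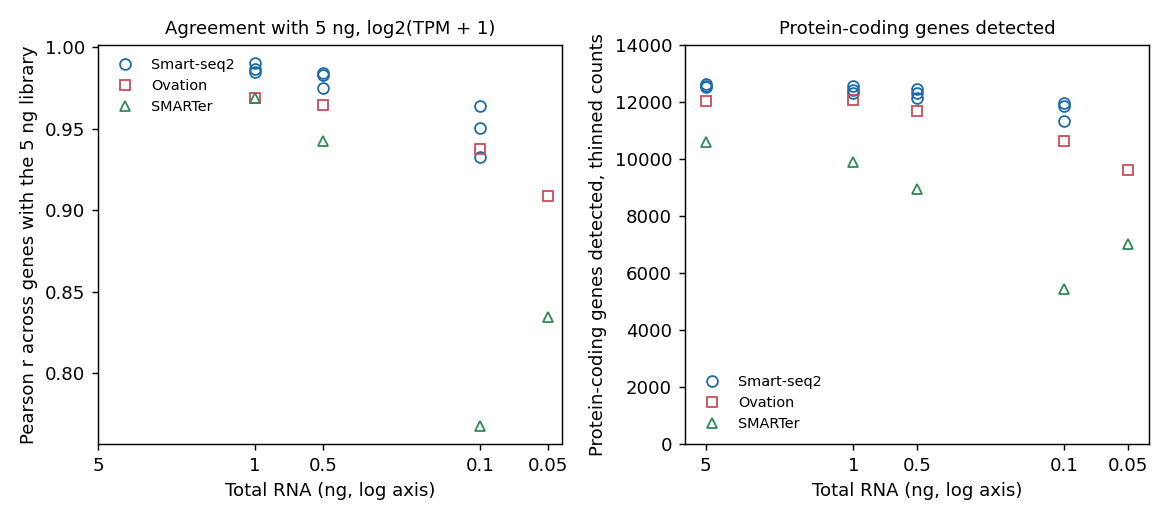
Pearson r with the 5 ng library of the same method (left) and protein-coding genes detected after thinning (right) against RNA input in ng, by method; points are libraries. At 0.1 ng r was 0.937 for Ovation, 0.767 for SMARTer and 0.949 on average for Smart-seq2.

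Seed storage and oil body genes were among the genes named by the rule between preparation methods, set side by side at 5, 1, 0.5 and 0.1 ng of bent-cotyledon RNA. The labels do not tie the kit libraries to the RNA of any Smart-seq2 replicate, so RNA and method are not separated. LCR11 (AT4G11485), for a small cysteine-rich peptide, was lower than in Smart-seq2 (1258 TPM on average) in both other methods, at 3.58 TPM in Ovation and 8.71 in SMARTer. In SMARTer the cell wall protein gene CWLP (AT3G22120) stood at 50.2 TPM against 0.615 in Smart-seq2, the flavonoid gene TT4 at 1526 against 213, and OLEO2 at 16332 against 2576. The water channel genes PIP1;4 (AT4G00430) and PIP1;5 (AT4G23400) stood at 2127 against 376 and at 72.1 against 10.9 TPM, and no longer met the rule with TPM rescaled over protein-coding genes, a setting chosen after seeing the data. Ribosomal RNA loci held 13.1 ± 1.42% of TPM in Smart-seq2 at 5 ng. Lower in SMARTer were the trehalose phosphatase gene TPPI (AT5G10100), at 6.004 against 115 TPM, the F-box gene FBS1 (AT1G61340), at 2.91 against 55.2, and 3xHMG-box2 (AT4G23800), of mitotic chromatin, at 29.0 against 154. In Ovation the other genes named by the rule were lower: CRA1 (19.0 against 1341 TPM), PSAH2 (AT1G52230), of photosystem I (11.5 against 847), SESA1 (1.25 against 126) and the plastid ribosomal gene RPL27 (AT5G40950) (5.17 against 342). Counted by a size rule without a test, since these kits have 1 library per input, 8126 of 32507 genes differed in Ovation, 13 higher and 8113 lower, and 179 in SMARTer, 41 higher and 138 lower. With the same rescaling, of the Ovation genes above LCR11, PSAH2 and SESA1 were still named by the rule while CRA1 and RPL27 were not.

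Ribosomal RNA loci held 78.6 to 85.4% of TPM in the Ovation libraries and 1.29 to 3.98% in SMARTer, so TPM was also rescaled over protein-coding genes, a setting chosen after seeing the data. Of the 27442 genes then considered, Ovation had 204 differing genes, 120 higher and 84 lower, and SMARTer 152, 10 higher and 142 lower. On that scale the cytokinin response gene RR3 (AT2G41310) stood at 192 TPM in Ovation against 2.40 in Smart-seq2 (SESA1 remained lower, at 27.9 against 217). ABCI5 (AT2G07771), a nuclear copy of a mitochondrial gene, and the glycine-rich protein gene GRP23 (AT2G32690) stood at 98.0 against 3.79 TPM and at 138 against 4.87. Oil body genes read higher than in Smart-seq2 in both kits on that scale, by a median log2 difference of 0.87 in Ovation and 0.94 in SMARTer, above 99.95% and 99.96% of 10000 random lists of like expression. Storage protein genes read lower in SMARTer, by a median of −1.47, above 0.03% of random lists, and silencing genes by −1.69, above 1.02%. Wound and handling genes read lower in Ovation, by −1.09, above 0.13%. On TPM as deposited the lists read lower in Ovation, oil body genes too: 6 of 7 were lower by the size rule and 0 higher, with a median of −2.81, above 99.26% of random lists. Storage protein genes were lower in 9 of 9 cases (median −4.84, above 1.17%), photosynthesis genes in 41 of 43 (−4.36, above 2.73%) and wound and handling genes in 11 of 13 (−3.105, above 0.22%). In SMARTer that scale gave medians of 1.47 for oil body (above 99.98%), −0.95 for storage protein (above 1.13%), 0.57 for photosynthesis (above 99.58%) and −1.16 for silencing genes (above 1.25%).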

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

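The tests of the 3 patterns in this part were chosen only after the results were seen. Spike-in RNAs, which enter no comparison above, took 0.0877 to 4.98% of counts in the stage libraries and 2.11 to 2.95% in the SMARTer libraries. Their mean was 3.94% at preglobular, and 0.177, 0.131 and 0.620% at globular, early heart and late heart. It was 3.43, 2.40, 1.64 and 1.98% at early torpedo, late torpedo, bent cotyledon and mature green. The steps from preglobular to globular and from late heart to early torpedo thus also differ in spike-in share. Non-coding RNAs outside the locus codes took 0.426 to 3.4% of counts in the stage libraries and 22.6 to 24.9% in the Ovation libraries. Both were noted because they are signal in data that the comparisons leave out; no control libraries exist for them, and the amount of spike-in added is not stated, so no explanation was tested.

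Heat shock genes such as HSP70 and HSFA2 stood higher in preglobular than in globular embryos, by a median log2 fold change of −3.95 over 8 genes on the way to globular. A stress response to opening the seed could raise them. Wound and handling genes had a median of −0.0158 (SD 1.88 over 16 genes), so that list did not fall as a whole. Its members spread too widely for this to decide on a wound response in part of them. A single preglobular library could also raise them, but in 7 of the 8 genes the stages did not overlap, each preglobular library lying above each globular one; chance gives 10% without overlap in either direction. Heat or delay during collection of the preglobular embryos stays open, as does wounding that moved only part of the wound list. So does a difference between the stages themselves, which was not tested.

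At bent cotyledon 123 genes, among them DEG14, stood at least 4-fold lower than at both late torpedo and mature green, and 51.2% of them were not protein-coding, against 5.99% of the tested genes. Their median gene length was 687 bases, against 2314, so effective transcript length is a candidate explanation. With an offset for it 86.2% of them were still called at least 4-fold lower, which leaves it open for the rest. Small nucleolar and spliceosomal RNA genes had a median log2 fold change of −2.41 into bent cotyledon and 1.53 out of it over 195 tested genes, a value that loss of short RNA from this RNA would need. Of these 195 genes 42 are among the 123. Non-coding RNAs outside the locus codes took 2.96 ± 0.711% of counts at bent cotyledon (SD, n = 3). They took 1.13 ± 0.337% at late torpedo and 2.21 ± 0.355% at mature green, shares not rescaled by TMM factors. Not all non-coding RNA thus fell into bent cotyledon. By the labels all stages came from counted embryos, and an amount of RNA is stated for bent cotyledon only. A difference in preparation therefore cannot be separated from the stage, and a change in these RNAs with development stays open.

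Early torpedo replicate 2 was closer to a late torpedo library than to its own stage. Where late heart is 0 and late torpedo is 1, it stood at 0.805 over 472 rising genes, with replicates 1 and 3 at 0.445 and 0.509, and at 0.779 over 43 falling genes, with 0.411 and 0.45. A swap with late torpedo replicate 2 would put that library among the early torpedo libraries, but it stood at 0.866 over 518 genes, against 0.4 and 0.46, which argues against a swap between the groups, although the split that exchanges these libraries called 1856 genes, against 238. By position, embryos further along within the stage and a single wrong label both stay open. Either gives this place in rising and in falling genes alike. Early torpedo replicate 2 had the storage protein genes CRU3 at 0.042, SESA2 at 24.2, SESA3 at 30.9 and CRA1 at 109 CPM. The lowest late torpedo values were 7.10, 147, 180 and 296 CPM. For these genes that argues against a late torpedo library under a wrong label, though the naming rule favours such gaps for all but CRU3. LHCB2.2 went the other way, at 1070 CPM against 719 to 1071, so a wrong label is not excluded. On axes that left out late torpedo replicates 1, 2 and 3 in turn, replicate 2 of early torpedo stood at 0.796, 0.792 and 0.811 and the library left out at 1.049, 0.866 and 1.028, a spread too wide to tell them apart.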

How the results depend on the processing

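Settings restricted to protein-coding genes were chosen only after the results were seen; the other alternatives were not. Of 12 counts of changed genes 3 stayed within 1.5 times their value under every alternative; the cause of each change below was not tested unless stated. Leaving out 1 replicate gave 1837 to 3432 genes from globular to early heart (3698 with all), 170 to 546 from early to late heart (515), 1280 to 4918 from late heart to early torpedo (4000), 44 to 1154 from early to late torpedo (238) and 0 to 708 from 5 to 0.1 ng (35). Asking for a 2-fold change, which can only lower a count, gave 2396 from preglobular to globular, 1679 to early heart, 1523 from late heart to early torpedo, 2952 from late torpedo to bent cotyledon and 7302 to mature green. Limma on log2(TPM + 1) called 9456 from preglobular to globular, 5582 to early heart, 9060 from late heart to early torpedo and 537 from early to late torpedo, and on log2(TPM + 0.1) 9229 and 8290 from preglobular to globular and from late heart to early torpedo. DESeq2 called 1008 from early to late heart, 699 from early to late torpedo, 434 from 5 to 0.1 ng and 1 from 5 to 0.5 ng, where no filter also gave 1. Fits of only the 2 groups, with fewer libraries to estimate spread, gave 1944 from early to late heart, 2336 from late heart to early torpedo, 3 from early to late torpedo and 0 from 5 to 0.1 ng. The 35 genes at 0.1 ng became 8 with the 5 CPM filter, 15 with RLE factors, 86 and 0 with limma at pseudocounts 0.1 and 1, and 0 with the replicate block that pairs libraries of the same RNA. In the other fits with the block, counts stayed within 1.5 times. At 0.1 ng r with the 5 ng library was 0.918 for Smart-seq2, 0.902 for Ovation and 0.700 for SMARTer with pseudocount 0.1, and 0.894, 0.888 and 0.741 over genes at 1 TPM in either library. Without organelle genes it was 0.929 and 0.763 for Ovation and SMARTer, with thinned counts 0.892 and 0.726, and over protein-coding genes 0.901 and 0.757. Size rules of 1 and 3 gave 12981 and 3173 differing genes in Ovation and 1165 and 69 in SMARTer, and pseudocount 0.1 gave 346 in SMARTer. Rescaling over protein-coding genes gave 204 in Ovation. That setting takes ribosomal RNA out of the total and also considers fewer genes, 27442 against 32507, and these were not separated. The list test of photosynthesis genes from 5 to 0.5 ng changed sign on log2(TPM + 1), at adjusted p = 0.98. Of 195 list tests 112 kept their call, or stayed uncalled, under every alternative, and 65 lost the call with an estimated correlation. A change of direction was counted only where at least 1 of the 2 fits called the list. Leaving out 1 replicate was the only alternative run for list medians. Under it no median of a list called by camera changed direction. Of 144 named gene changes 123 kept their call under every alternative, and none of the 144 reversed. The lowest depth was 1021484 counts, at 0.1 ng; whether depth limits the calls there was not tested.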

Other observations

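Tests in this part on other splits of the libraries were chosen only after the results were seen, as were the genes named from the bent-cotyledon pattern. Apart from the genes low at bent cotyledon, 35 genes stood at least 4-fold higher there than at both late torpedo and mature green. RHM1 (AT1G78570), which makes rhamnose for pectin and flavonoids, stood at 131 ± 56.6 CPM (SD, n = 3), against 21.3 ± 3.66 and 27.0 ± 3.75. The ethylene response factor gene ERF13 (AT2G44840) stood at 30.3 ± 5.85 against 7.21 ± 5.08 and 3.37 ± 1.47. ESM1 (AT3G14210), which directs glucosinolate breakdown, and MYB28 (AT5G61420), which switches on glucosinolate synthesis, stood at 20.6 ± 1.36 and 1.304 ± 0.0713 CPM, against 1.28 ± 0.381 and 0.239 ± 0.0657 at late torpedo. DIR1, the ubiquitin ligase gene PUB19 (AT1G60190) and the jasmonate regulator MYC2 are also among them. The rise of MYC2 was not called by DESeq2 (adjusted p = 0.408), with the replicate block (adjusted p = 0.0581), without bent cotyledon replicate 1 or 2 (adjusted p = 0.0729 and 0.065) or without late torpedo replicate 1 or 2 (adjusted p = 0.0843 and 0.0788). Of the 35 genes 8.57% were not protein-coding. No explanation was tested for them.

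LEC1 fell along the series while its relative NF-YB6 fell at the first step, rose from late heart to bent cotyledon, reaching 736 ± 118 CPM (SD, n = 3), and stood at 144 ± 76.0 CPM at mature green.

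Other splits of the same libraries were counted for each comparison of gene levels. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, so only the values are given. The real split called 4961, 3698, 515, 4000, 7007, 11648 and 15949 genes from preglobular to globular, globular to early heart, early to late heart, late heart to early torpedo, late torpedo to bent cotyledon, bent cotyledon to mature green and preglobular to mature green. The highest other split called 12, 0, 0, 0, 1, 6 and 25, and in each case 1 split, the real one, called as many. From 5 to 0.1 ng the real split called 35 and the highest other 0, again 1 split. From 5 to 1 ng and from 5 to 0.5 ng all 10 splits called 0. The input splits do not keep libraries of the same RNA paired, and the fit with the replicate block called none at 0.1 ng. From early to late torpedo 2 of 10 splits called as many as the real 238. The other set early torpedo 1 and 3 with late torpedo 2 against early torpedo 2 with late torpedo 1 and 3 and called 1856, which points to a structure of the samples beyond their stage. Over the 8 stages 1 of 100 regroupings of the 24 libraries, the real one, called 19141 genes, with 3207 in the highest other. That is the smallest share that 100 regroupings can give, and it makes chance unlikely there without excluding it. The regroupings treat all libraries as separate collections, which is unsure at mature green.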
